A study of Rattus norvegicus with 18 samples.

How the data were processed

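The deposited values are probe set signals on a linear intensity scale, produced per the labels with MAS5 (version not given in the sources used here) from 1-colour Affymetrix rat 230A arrays. Each array had been scaled by the authors to a 2% trimmed mean of 500.1, so no further scaling was applied. GeneSpring 7.2 is named by the authors for their later analysis, and no trace of per-gene centring was found in the values. The file held 15923 probe sets and 18 arrays in 5 groups, 6 controls and 3 lungs in each of 4 operated groups. The 57 control probe sets were left out. Values were analysed as log2(signal + 25), the pseudocount being 5% of the trimmed mean, and a probe set was tested if at least 3 arrays lay above the 40th percentile of all signals (173.6), which left 10533.

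Gene names came from the platform annotation, dated August 2016, and were checked through the Entrez identifier against a current RefSeq gene table, which changed 0 symbols. The annotation gave 1 symbol for 12783 probe sets, several for 312 and none for 2771, and only probe sets with 1 symbol were named. For named genes and gene lists each gene was represented by its tested probe set of highest mean value, giving 7728 genes.

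Comparisons were fitted with limma 3.58.1 in R 4.3.3, using lmFit and eBayes with default priors on 5 group means over all 18 arrays. Tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method within each comparison, and probe sets with an adjusted p under 0.05 were counted as higher or lower. The comparisons, the filter, the pseudocount, the thresholds, the gene lists and most alternatives were chosen before the data were examined. Fits without the arrays of high actin ratio, fits with the actin ratio or the cardiac marker mean as a covariate, and list tests that left out 1 array at a time were added after seeing the data. Errors of log2 differences are limma standard errors, and fold changes refer to the log2(signal + 25) scale, which understates the change of genes of low signal. Where the mean signal of a group was about 25 or less the pseudocount would fix the fold and the rank, so mean signals are given in place of a fold.

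Genes were named by fixed rules. In each comparison these were the largest rises and the largest falls among called genes, up to 8 of each against control and up to 5 elsewhere. Outside the change of the left-right difference, only genes in which every array of the first group lay on the same side of the mean of the second could be named this way. From each gene list the 4 passing members with the smallest adjusted p could be named, and all of them where at most 5 passed. Of 36 gene lists written in advance, 33 had at least 5 measured members and were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the lists of each comparison. Camera with an estimated correlation and fry were run as alternatives. Members were counted as rising or falling by the adjustment over all probe sets, and again with an adjustment over the list alone. Of the 7728 genes, 668 were called higher and 736 lower than control in the left lungs at 30 min, and 1044 and 1864 at 3 h. In the right lungs these numbers were 458 and 489 at 30 min, and 599 and 975 at 3 h. Counts of list members against control are to be read beside them. Array measures were compared by exact permutation tests in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and figures were drawn with matplotlib 3.10.9.

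The scripts were tested on simulated arrays with the spread of each probe set and 200 changed probe sets of 10533, in 10 simulations per comparison. For left 3 h versus control 87.8% of 2-fold and 98.7% of 4-fold changes were recovered, with 4.99% of calls false. For left versus right at 3 h these values were 78.5%, 98.2% and 5.05%, and for the change of the left-right difference 52.5%, 93.6% and 4.63%. A list shifted in every member was found in 10 of 10 simulations in each comparison, with 0, 1 and 1 other lists called. Genes were drawn independently of each other in these simulations. They therefore do not show how often list tests call falsely among genes that vary together, as in real arrays.

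The right lungs came from the same rats as the left lungs, but the labels do not say whether replicate numbers mark rats, so no pairing was used. Deviations from the group means correlated at 0.12, 0.31 and 0.15 between left and right lungs of the same number at 30 min, and at -0.17, 0.07 and -0.15 at 3 h. Lungs of unlike number correlated at -0.29 to 0.1 at 30 min and at -0.24 to 0.34 at 3 h. The numbers may therefore not match rats at 3 h. Fits with the replicate number as a block were run as alternatives.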

Results

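Gene expression was measured in 18 lungs of male Sprague-Dawley rats on 1-colour Affymetrix rat arrays, 1 lung per array. Left lungs had spent 2 h without blood flow under a hilar clamp, in place and warm, and were then reperfused for 30 min (n = 3) or 3 h (n = 3). The right lungs, which were not clamped, were collected at the same times (n = 3 and n = 3), and 6 normal lungs from 6 rats, collected right after sacrifice, were the controls. The labels do not say from which side the control lungs came, or whether their arrays were run with the operated ones. A comparison with control may therefore include a difference between the sides. All clamped lungs were left lungs and all unclamped operated lungs were right lungs. Comparisons of left with right therefore cannot tell the clamp from the side. The design asks which transcripts move in the clamped lung after blood flow returns, and what happens meanwhile in the lung on the other side. No lung was collected after the clamp without reperfusion, so effects of the clamp and of returning blood flow cannot be told apart. Of 15923 probe sets, 10533 passed the low-signal filter and were tested, and they covered 7728 genes. The median signal per array ran from 232.3 to 283.8. It averaged 243 ± 15.2 (SD, n = 3) in the left lungs at 3 h and 275 ± 7.92 (SD, n = 6) in the controls. The exact permutation p, two-sided, was 0.0238 (adjusted p = 0.122). The share of higher calls against control is therefore also given with each array centred on its median. The precision of every value below is limited by the number of arrays. The p-values measure the spread between lungs of separate rats within a group, while the left and right lungs of a time came from the same rats.

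The arrays differed in RNA quality and in the tissue on them. The ratio of the 3' to the 5' beta-actin probe set, which rises when RNA is degraded, was 4.81 in left 30 min replicate 1, 2.93 in right 30 min replicate 3 and 2.30 in left 30 min replicate 3, against 1.31 to 1.78 in the other arrays. The left 30 min lungs averaged 2.88 ± 1.72 (SD, n = 3) and the controls 1.43 ± 0.0922 (SD, n = 6), with an exact permutation p = 0.0476, two-sided (adjusted p = 0.19 over 36 such tests). The mean log2 signal of 12 cardiac muscle markers ranged from 6.32 to 8.70 among the controls, from 6.37 to 6.84 in the left lungs at 3 h and from 8.13 to 10.1 in the right lungs at 3 h. The mean of 8 erythroid markers was 10.3 ± 0.379 (SD, n = 3) in the right lungs at 30 min against 9.38 ± 0.187 (SD, n = 6) in the controls. The exact permutation p was 0.0238, the smallest that this two-sided test, which doubles the smaller tail, gives for 3 against 6 arrays (adjusted p = 0.122). The mean of 11 neutrophil markers was above every control in all 12 operated lungs.

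**Figure D1:**
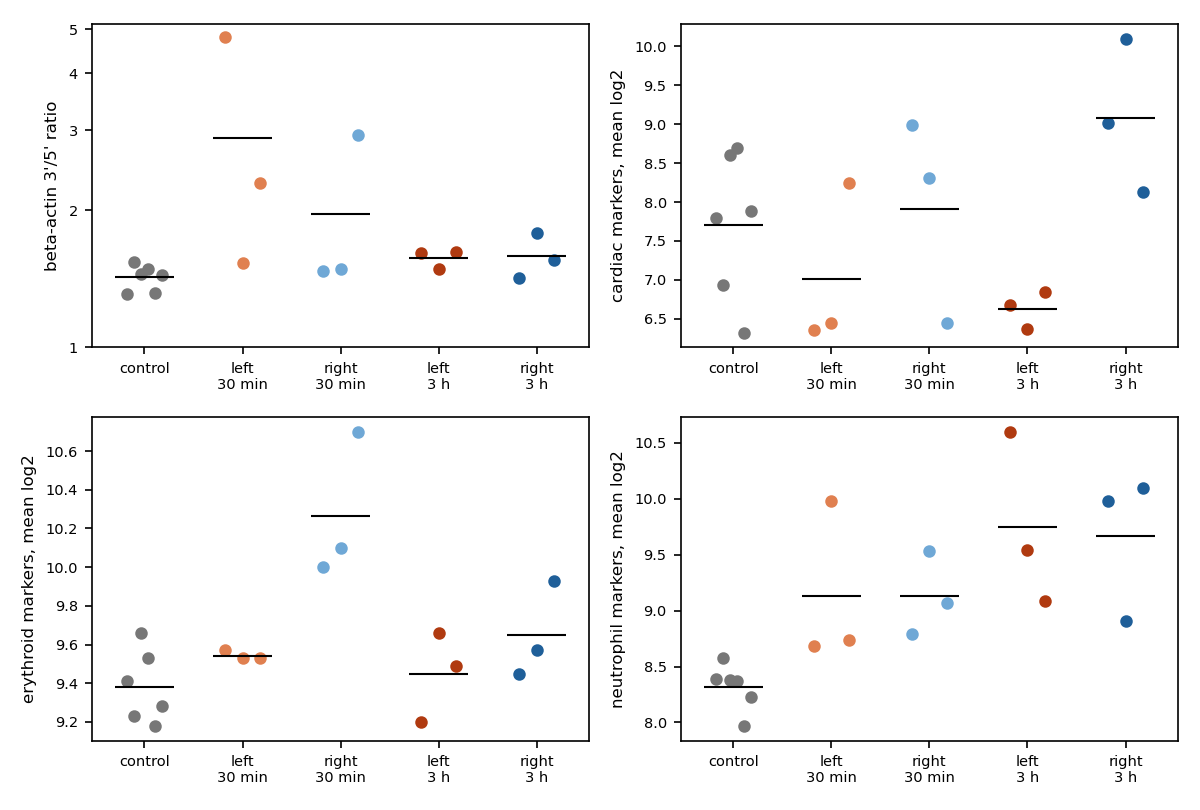
Beta-actin 3' to 5' ratio (log axis) and mean log2 signal of the cardiac, erythroid and neutrophil markers, 1 point per array, with the 5 groups on the x axis and the group mean as a bar. 3 of the 30 min arrays lie above a ratio of 2, and the cardiac marker mean of the left lungs at 3 h (6.37 to 6.84) lies below that of the right lungs at 3 h (8.13 to 10.1).

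In clamped left lungs reperfused for 30 min, inflammatory messengers and early response genes were far above control (n = 3 against 6). The chemokine Ccl2 was 16.5-fold higher (log2 difference 4.04 ± 0.44, SE, limma adjusted p = 1.3e-05). The EGF receptor ligand Areg was 16.4-fold (4.04 ± 0.45, adjusted p = 1.5e-05), the cytokine Il6 16.0-fold (adjusted p = 8e-05) and the metallothionein Mt2A 13.3-fold higher (3.74 ± 0.32, adjusted p = 1.5e-06). The largest rises also took in the protease inhibitor Tfpi2 (11.8-fold), the serine protease Prss22 (9.45-fold) and the AP-1 factors Fosb (log2 3.58 ± 0.93) and Fos (7.78-fold). The controls scattered widely in both AP-1 factors, with mean signals of 306 ± 370 for Fosb and 869 ± 909 for Fos (SD, n = 6). Prkaa2, a catalytic subunit of the energy sensor AMPK, fell from a mean signal of 250 ± 85.1 to 6.83 ± 0.513 (SD, adjusted p = 3.8e-07), under the 5th percentile of all signals (8.816), so no fold is given. Cdkn2b fell 5.16-fold, the BMP receptor Bmpr2 4.34-fold, the type I cell gene Akap5 3.87-fold, the transcription factors Creb1 and Foxo1 3.44-fold and 3.29-fold, the B-cell receptor chain Cd79b 3.30-fold and the Wnt co-receptor Lrp6 3.20-fold. The log2 difference of Cdkn2b moved from -2.37 to -3.24 without left 30 min replicate 3.

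By group, 16 of 24 immediate early transcription factors rose and 1, Klf2, fell in these lungs (18 and 1 adjusted over the list alone, camera adjusted p = 4.3e-09, adjusted p = 0.32 with an estimated correlation). Among them Myc was 3.72-fold and Fosl1 3.98-fold above control. Of 21 cytokines and chemokines 9 rose (11 higher and 2 lower adjusted over the list alone, adjusted p = 3.3e-05, adjusted p = 0.32 with an estimated correlation), with Cxcl1 at 6.68-fold. Among 16 NF-kB targets 9 rose (9 over the list alone, adjusted p = 3.6e-05, adjusted p = 0.32 with an estimated correlation), with Nfkbia at 2.19-fold. Apoptosis and p53 genes rose in 9 of 18 (10 over the list alone, adjusted p = 2e-06, adjusted p = 0.16 with an estimated correlation), led by Bcl2l1 at 3.73-fold and Gadd45g at 4.50-fold. Glucocorticoid responsive genes rose in 10 of 20 and fell in 1 (13 and 1 over the list alone, adjusted p = 1.2e-07, adjusted p = 0.16 with an estimated correlation), with Fkbp5 at 5.75-fold and Klf9 at 2.40-fold. Of 21 coagulation and endothelial activation genes 7 rose (8 higher and 1 lower over the list alone, adjusted p = 7e-05, adjusted p = 0.32 with an estimated correlation), with tissue factor F3 at 4.32-fold.

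Interferon response genes rose in 5 of 23 in the left lungs at 30 min (5 over the list alone, adjusted p = 0.002, adjusted p = 0.46 with an estimated correlation). Matrix protease and remodelling genes rose in 5 of 21 and fell in 1 (the same over the list alone, adjusted p = 0.012, adjusted p = 0.32 with an estimated correlation). Neutrophil markers rose in 4 of 11 and fell in 1 (the same over the list alone, adjusted p = 0.024, adjusted p = 0.78 with an estimated correlation). S100a8 was 6.20-fold and S100a9 4.33-fold above control. Mast cell and basophil markers were lower, with Kit and Cpa3 falling among 5 (3 over the list alone, adjusted p = 0.044, adjusted p = 0.32 with an estimated correlation). Of 18 heat shock genes 2 rose, Hspa1a at 1.78-fold and Dnajb1 at 1.42-fold, and Hspa4 fell (2 and 1 over the list alone, adjusted p = 0.78). The Hspa1a and Dnajb1 calls at this time each ended without any 1 of 6 arrays. Over all probe sets 916 were higher and 1183 lower, 43.6% of the calls being higher, and 62.2% when each array was centred on its median. Without left 30 min replicate 1, the array of highest actin ratio, 1309 probe sets passed and the Fosb call ended. Without replicate 2 the interferon, matrix protease and neutrophil list calls ended, at adjusted p = 0.052, 0.06 and 0.38. The mast cell call ended without control replicate 3 or left replicate 3. Without the 3 arrays of high actin ratio the left 30 min group was a single lung, assumed to vary like the other groups, and 637 probe sets passed. Fosb (log2 difference 3.71 ± 1.46, SE), Fos (2.97 ± 1.23), Akap5 (-2.23 ± 0.78) and Cd79b (-1.19 ± 0.53) did not pass in it, against 3.58 ± 0.93, 2.96 ± 0.76, -1.95 ± 0.48 and -1.72 ± 0.34 with all arrays. Nor did Nfkbia (1.06 ± 0.35 from 1.13 ± 0.21), Hspa1a (0.96 ± 0.37 from 0.83 ± 0.27), Dnajb1 (0.61 ± 0.26 from 0.51 ± 0.17), Kit (-0.84 ± 0.33 from -0.94 ± 0.20), Cpa3 (-0.72 ± 0.34 from -0.92 ± 0.27) or the mast cell list. With so few arrays these lost calls alone do not show a dependence on RNA quality. With all 18 arrays and the actin ratio as a covariate, 1194 probe sets passed, against 2099 without it. That ratio averaged higher in these lungs than in the controls, so this fit cannot tell RNA quality and the clamp apart.

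After 3 h of reperfusion the left lungs added a heat shock response to the inflammatory one (n = 3 against 6). The inducible chaperone Hspa1a was 10.4-fold above control (log2 difference 3.38 ± 0.27, SE, limma adjusted p = 3e-07), Hsph1 5.77-fold, Dnajb1 5.24-fold (2.39 ± 0.17, adjusted p = 9.5e-08) and Dnaja1 4.17-fold. The decoy interleukin 1 receptor Il1r2 rose 21.4-fold (4.42 ± 0.46, adjusted p = 3.8e-06), and other large rises were in Mt2A (log2 4.17 ± 0.32), Il6 (16.8-fold), Areg (log2 3.90 ± 0.45), Tfpi2 (14.9-fold), Ccl2 (11.9-fold) and Fosb (10.9-fold). Without left 3 h replicate 1 the log2 differences of Il1r2 (4.42), Il6 (4.07), Tfpi2 (3.90) and Ccl2 (3.57) were 3.80, 3.26, 3.30 and 2.95, all still called. Bmpr2 was 5.43-fold below control. The mean signal of Prkaa2 fell from 250 ± 85.1 to 7.45 ± 1.49 (SD, adjusted p = 1.3e-07), under the 5th percentile, and that of Arhgef40 from 196 ± 44.9 to 25.9 ± 9.64 (SD, adjusted p = 0.00066). Other large falls were in Mn1 (4.19-fold), Nfix (4.01-fold), the Wnt feedback gene Axin2 (3.92-fold), the nuclear receptor Nr2f2 (3.78-fold) and Chtf8 (3.73-fold).

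The tested probe sets as a whole were lower by 0.12 on the log2 scale in the left lungs at 3 h, and the median of each gene group is given relative to that shift. Of 18 heat shock genes 14 rose and Hspa4 fell (14 and 1 adjusted over the list alone, relative median 1.29, camera adjusted p = 7.1e-12, adjusted p = 0.083 with an estimated correlation). Immediate early factors rose in 15 of 24 and fell in 1 (17 and 1 over the list alone, 1.13, adjusted p = 1.3e-07, adjusted p = 0.35 with an estimated correlation). Cytokines and chemokines rose in 12 of 21 and fell in 2 (12 and 2 over the list alone, 1.04, adjusted p = 3.7e-06, adjusted p = 0.11 with an estimated correlation). NF-kB targets rose in 11 of 16 (13 over the list alone, 0.76, adjusted p = 5.3e-08, adjusted p = 0.1 with an estimated correlation), with Socs3 at 3.79-fold and Sod2 at 3.67-fold. Coagulation and endothelial activation genes rose in 12 of 21 (14 higher and 1 lower over the list alone, 1.02, adjusted p = 1.3e-07, adjusted p = 0.1 with an estimated correlation), among them Plaur at 7.71-fold and F3 at 6.02-fold. Hypoxia and glycolysis genes rose in 17 of 28 and fell in 1 (18 and 1 over the list alone, 0.70, adjusted p = 1.3e-07, adjusted p = 0.083 with an estimated correlation), with the lactate transporter Slc16a3 at 3.53-fold and the glucose transporter Slc2a3 at 4.52-fold.

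Apoptosis and p53 genes rose in 9 of 18 (9 over the list alone, 0.65, adjusted p = 3e-06, adjusted p = 0.083 with an estimated correlation), with Gadd45a at 3.74-fold. The unfolded protein and integrated stress response rose in 11 of 27 and fell in 1 (12 and 1 over the list alone, 0.47, adjusted p = 2.8e-05, adjusted p = 0.083 with an estimated correlation), with Atf4 at 2.52-fold and the endoplasmic reticulum chaperone Hspa5 at 2.24-fold. Glucocorticoid responsive genes rose in 10 of 20 and fell in 1 (12 and 1 over the list alone, 0.84, adjusted p = 1.9e-06, adjusted p = 0.083 with an estimated correlation). Matrix protease and remodelling genes rose in 11 of 21 and fell in 2 (12 and 2 over the list alone, 0.71, adjusted p = 0.00022, adjusted p = 0.083 with an estimated correlation), with Timp1 at 6.12-fold. Proteasome genes rose in 6 of 34 and fell in 1 (5 higher over the list alone, 0.30, adjusted p = 0.00078, adjusted p = 0.43 with an estimated correlation). Oxidative stress genes were split, 6 rising and 2 falling of 17 (6 and 2 over the list alone). Their list test was positive (adjusted p = 0.024, adjusted p = 0.25 with an estimated correlation), with a relative median of 0.16 that was 0.03 under quantile normalization, which ended the list call. Hmox1 rose 5.78-fold and Txnrd1 2.72-fold. Neutrophil markers rose in 5 of 11 and Cxcr1 fell (6 and 1 over the list alone, 0.83, adjusted p = 0.00022, adjusted p = 0.4 with an estimated correlation).

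Alveolar type II cell markers fell in 6 of 14 in the left lungs at 3 h, with none rising (6 over the list alone, relative median -0.20, adjusted p = 0.024, adjusted p = 0.53 with an estimated correlation). Muc1 was 2.77-fold, the lineage factor Nkx2-1 2.56-fold and the lipid transporter Abca3 2.22-fold below control. Over all probe sets 1456 were higher and 2521 lower, 36.6% of the calls being higher, and 60.8% when each array was centred on its median. Without left 3 h replicate 1 the count was 2299 and the type II cell list lost its call (adjusted p = 0.13).

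**Figure D2:**
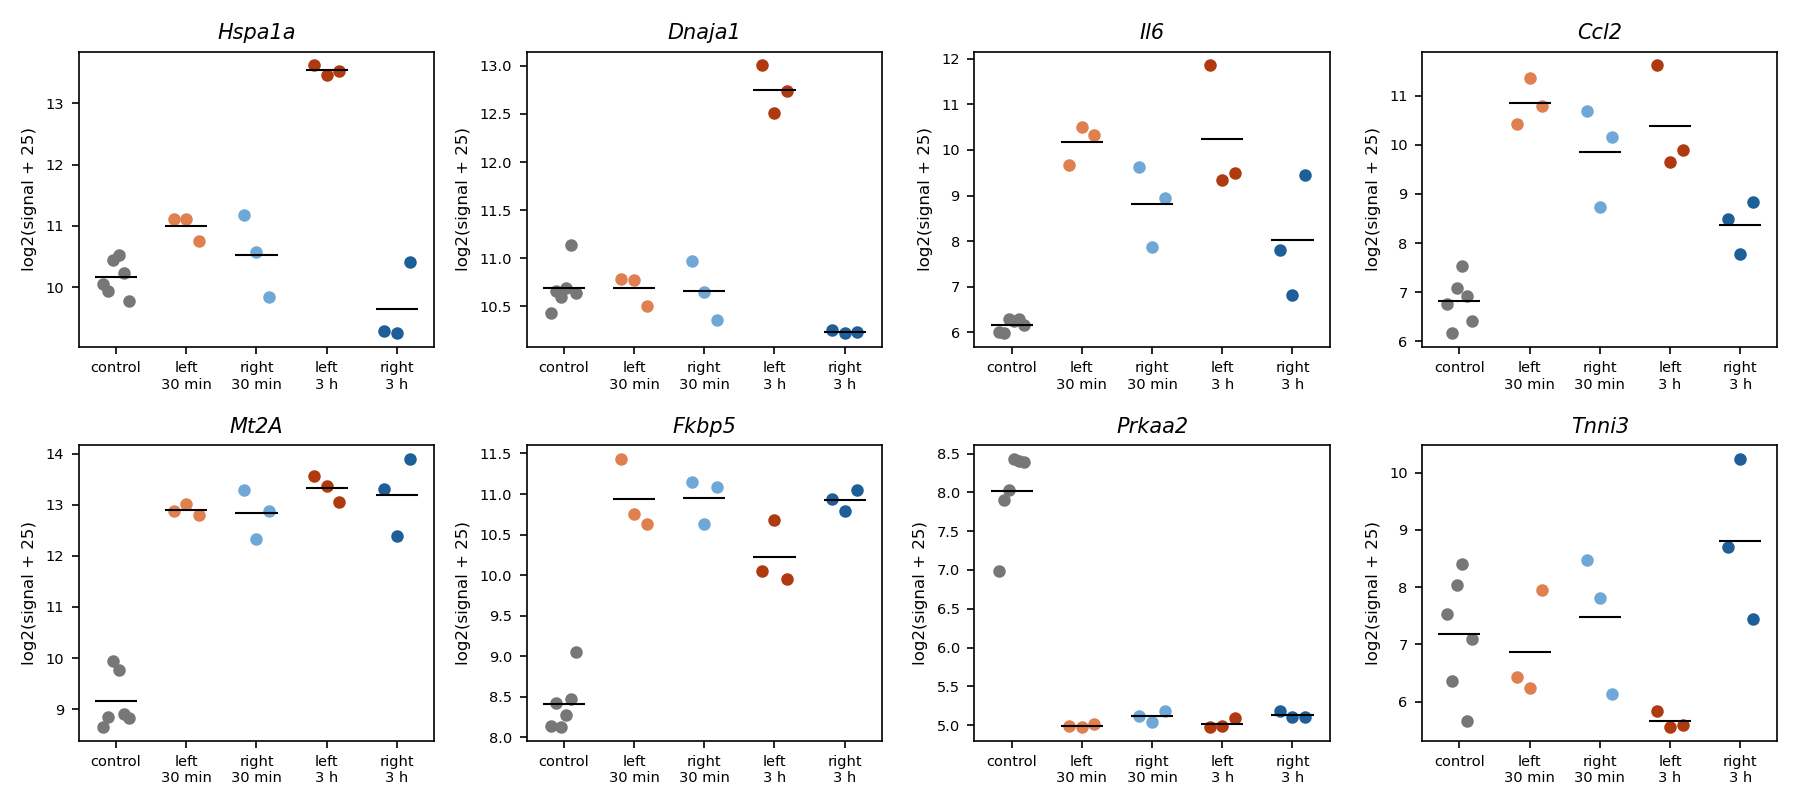
Log2(signal + 25) of 8 genes, 1 point per array, with the 5 groups on the x axis and the group mean as a bar. Hspa1a and Dnaja1 are high in the left lungs at 3 h, Il6, Ccl2, Mt2A and Fkbp5 are above control in operated lungs, Prkaa2 is below control in every operated lung, and Tnni3 spreads widely in every group but the left lungs at 3 h.

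The unclamped right lungs also departed from control at 30 min (n = 3 against 6). Mt2A was 12.8-fold higher (log2 difference 3.68 ± 0.32, SE, limma adjusted p = 2e-06), Ccl2 8.22-fold (3.04 ± 0.44, adjusted p = 0.00025), Areg 7.51-fold, Il6 6.26-fold, the neutrophil chemokine Cxcl1 5.89-fold, the glucocorticoid-induced co-chaperone Fkbp5 5.80-fold (2.54 ± 0.22, adjusted p = 2e-06), Il1r2 5.61-fold and S100a8 5.51-fold. The mean signal of Prkaa2 fell from 250 ± 85.1 to 9.61 ± 1.80 (SD, adjusted p = 5.5e-07), close to the 5th percentile. Bmpr2 was 4.71-fold lower, and Akap5 (4.03-fold), Zfpm1 (3.43-fold), Veph1 (3.16-fold), Foxo1 (3.10-fold), Cd79b (3.04-fold) and the granzyme Gzmm (3.03-fold) were also among the large falls.

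Glucocorticoid responsive genes rose in 7 of 20 and fell in 1 in the right lungs at 30 min (10 and 1 adjusted over the list alone, camera adjusted p = 5.3e-06, adjusted p = 0.33 with an estimated correlation). Apoptosis and p53 genes rose in 7 of 18 (8 over the list alone, adjusted p = 0.00021, adjusted p = 0.33 with an estimated correlation). Cytokines and chemokines rose in 7 of 21 (9 higher and 2 lower over the list alone, adjusted p = 0.00044, adjusted p = 0.47 with an estimated correlation). Immediate early factors rose in 4 of 24 and Klf2 fell (9 and 1 over the list alone, adjusted p = 1.7e-05, adjusted p = 0.52 with an estimated correlation). Coagulation genes rose in 6 of 21 (8 over the list alone, adjusted p = 0.003, adjusted p = 0.52 with an estimated correlation). Interferon genes rose in 3 of 23 (3 over the list alone, adjusted p = 0.007, adjusted p = 0.52 with an estimated correlation). Matrix genes rose in 5 of 21 (5 over the list alone, adjusted p = 0.0068, adjusted p = 0.36 with an estimated correlation). Neutrophil markers rose in 4 of 11, with 1 falling (4 and 1 over the list alone, adjusted p = 0.007, adjusted p = 0.56 with an estimated correlation). Erythroid genes rose in 5 of 8 (5 over the list alone, adjusted p = 3.2e-05, adjusted p = 0.33 with an estimated correlation), among them the red cell anion exchanger Slc4a1 at 3.35-fold and the haem synthesis enzyme Alas2 at 3.07-fold. Alveolar type I markers fell in 5 of 10 (5 over the list alone, adjusted p = 0.007, adjusted p = 0.52 with an estimated correlation). Among these Aqp5 was 1.75-fold and Ager 1.38-fold lower (-0.80 ± 0.20 and -0.46 ± 0.12, SE). Without the 3 arrays of high actin ratio, of which right 30 min replicate 3 is in this comparison, they stood at -0.70 ± 0.24 and -0.33 ± 0.13 and did not pass, nor did Zfpm1 (-1.56 ± 0.58). The type I markers Emp2 (-0.31 ± 0.12 from -0.34 ± 0.11) and Pdpn (-0.28 ± 0.13 from -0.36 ± 0.12) did not pass in that fit either. Lymphocyte markers fell in 4 of 15 (5 over the list alone, adjusted p = 0.0033, adjusted p = 0.56 with an estimated correlation). Over all probe sets 639 were higher and 768 lower, 45.4% of the calls being higher, and 57.0% with each array centred on its median. Without right 30 min replicate 1 the count was 811 and the coagulation and interferon list calls ended, and without replicate 2 that of the neutrophil list. The Zfpm1 and Gzmm calls each ended without 2 or more single arrays.

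In the right lungs at 3 h Mt2A stayed 16.5-fold above control (log2 difference 4.04 ± 0.32, SE, limma adjusted p = 5.3e-07, n = 3 against 6). The mean signal of the protease inhibitor Serpinb2 rose from 21.6 ± 11.6 to 441 ± 419 (SD, adjusted p = 0.0026), with log2 differences from 1.99 to 3.76 when 1 array was left out. Il1r2 stood at 13.7-fold, S100a8 at 7.99-fold, Fkbp5 at 5.69-fold, S100a9 at 5.13-fold, the metalloproteinase inhibitor Timp1 at 4.99-fold and myoglobin Mb at 4.64-fold. The Mb call (2.21 ± 0.72, adjusted p = 0.037) ended without any 1 of 5 arrays, control replicates 1, 2 and 5 and right 3 h replicates 1 and 2. The mean signal of Prkaa2 fell from 250 ± 85.1 to 10 ± 0.975 (SD, adjusted p = 5.3e-07) and that of Gzmm from 246 ± 77.0 to 25.7 ± 13.0 (SD, adjusted p = 0.0022). Bmpr2 was 5.23-fold, Tgfb1 4.78-fold and the actin-associated Palld 4.55-fold lower, followed by Arhgap32 (4.06-fold), Nfix (4.05-fold) and Foxo1 (3.99-fold). The log2 difference of Tgfb1 moved from -2.26 to -1.60 without right 3 h replicate 2, and was still called. Of 18 heat shock genes 1 rose and 3 fell (1 and 3 adjusted over the list alone, camera adjusted p = 0.56).

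Glucocorticoid responsive genes rose in 10 of 20 and fell in 1 in the right lungs at 3 h (12 and 1 adjusted over the list alone, camera adjusted p = 5.4e-08, adjusted p = 0.14 with an estimated correlation). Monocyte and macrophage markers rose in 7 of 12 (7 higher and 1 lower over the list alone, adjusted p = 0.0016, adjusted p = 0.15 with an estimated correlation). The phagocyte oxidase chain Cybb stood at 2.19-fold and Cd14 at 3.73-fold. Neutrophil markers rose in 5 of 11 (5 over the list alone, adjusted p = 8.2e-05, adjusted p = 0.4 with an estimated correlation). Coagulation genes rose in 8 of 21 (9 over the list alone, adjusted p = 0.00035, adjusted p = 0.38 with an estimated correlation). Apoptosis and p53 genes rose in 7 of 18 and fell in 1 (7 and 1 over the list alone, adjusted p = 0.0039, adjusted p = 0.38 with an estimated correlation). Oxidative stress genes rose in 5 of 17 and fell in 1 (5 and 1 over the list alone, adjusted p = 0.0031, adjusted p = 0.29 with an estimated correlation). Proteasome genes rose in 9 of 34 (11 higher and 1 lower over the list alone, adjusted p = 3.8e-05, adjusted p = 0.38 with an estimated correlation). Cytokines rose in 5 of 21 and fell in 1 (5 and 1 over the list alone, adjusted p = 0.016, adjusted p = 0.49 with an estimated correlation). Hypoxia genes rose in 6 of 28 and fell in 2 (8 and 3 over the list alone, adjusted p = 0.0086, adjusted p = 0.45 with an estimated correlation). Matrix genes rose in 8 of 21 and fell in 2 (8 and 2 over the list alone, adjusted p = 0.016, adjusted p = 0.38 with an estimated correlation). Lymphocyte markers fell in 7 of 15 (9 over the list alone, adjusted p = 0.0016, adjusted p = 0.5 with an estimated correlation), including the T-cell kinase Lck at 2.16-fold lower.

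Oxidative phosphorylation genes rose in 9 of 83 and fell in 2 in the right lungs at 3 h (5 and 2 adjusted over the list alone, camera adjusted p = 3.8e-05, adjusted p = 0.49 with an estimated correlation). In the same arrays cardiac markers were higher by a median of 1.46 on the log2 scale (1 of 12 rose, none over the list alone, adjusted p = 0.00044, adjusted p = 0.49 with an estimated correlation). Ribosomal protein genes rose in 2 of 41 (none over the list alone, adjusted p = 0.0045, adjusted p = 0.71 with an estimated correlation), with a median of 0.10 that turned to -0.02 under quantile normalization. Over all probe sets 868 were higher and 1387 lower, 38.5% of the calls being higher, and 55.9% with each array centred on its median. Without right 3 h replicate 3 the count was 1417 and the cytokine, hypoxia, matrix and ribosomal list calls ended (adjusted p = 0.2, 0.2, 0.2 and 0.1). With the cardiac marker mean as a covariate 1328 probe sets passed and the cytokine and cardiac list calls ended.

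Differences from control went the same way in the left and right lungs in many probe sets. Across the 10533 probe sets, which are not independent replicates, the log2 differences from control correlated at r = 0.824 between the sides at 30 min and r = 0.758 at 3 h. Both comparisons use the same 6 controls, and simulated unchanged groups gave r = 0.335 and 0.331. The covariance was 0.147 at 30 min and 0.185 at 3 h against a simulated 0.013 at each time, and splitting the controls between the sides left r at 0.743 and 0.699. At 30 min 449 probe sets were higher on both sides (55.6 for independent lists), 513 lower on both (86.3) and 0 opposite by limma. At 3 h 634 were higher on both (120), 1097 lower on both (332) and 10 opposite. The numbers for independent lists make no allowance for the shared controls, which favour calls in the same direction over opposite ones. In all 4 comparisons with control 291 probe sets were higher, Mt2A and Fkbp5 among them, and 348 were lower, including Prkaa2, Bmpr2 and Foxo1. On the first principal component the control arrays stood apart from all operated ones. A batch or handling difference of the controls can therefore not be told apart from a change of both lungs.

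**Figure D3:**
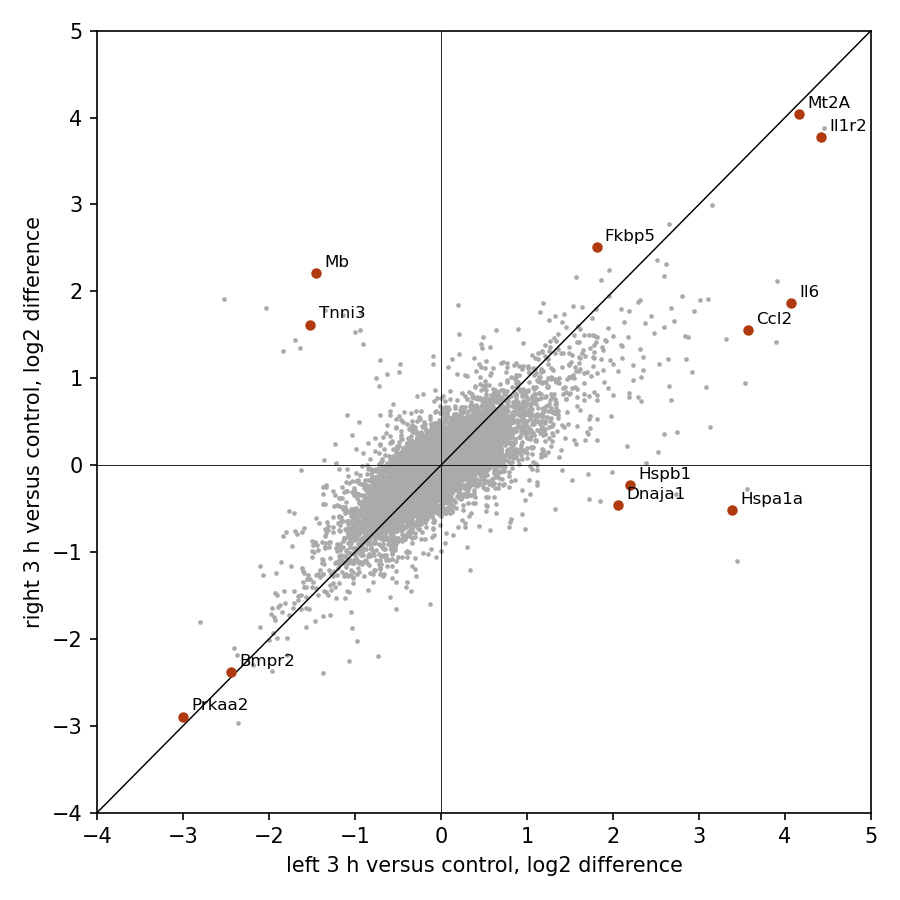
Log2 difference from control in the left lungs (x axis) against the right lungs (y axis) at 3 h, 1 point per tested probe set, with named genes marked and the line of equality drawn. Most points follow the line (r = 0.758), and heat shock genes such as Hspa1a and Dnaja1 lie far to the right of it.

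At 30 min the clamped and unclamped lungs of the same rats differed in few single genes (n = 3 against 3). The ubiquitin ligase Mylip was 2.15-fold higher in the left lungs (log2 difference 1.10 ± 0.14, SE, limma adjusted p = 0.0032), and Mief1 was 2.05-fold (-1.03 ± 0.15), Rnf144b 1.83-fold (-0.87 ± 0.14) and the BMP target Id1 1.80-fold lower (-0.85 ± 0.13), each at adjusted p = 0.015. These 4 were all the calls, against 906 of 10533 probe sets at an unadjusted p under 0.05, where chance alone gives about 1 in 20. Erythroid markers were lower on the left, with a median of -1.02 and 0 of 8 genes passing over all genes (5 lower adjusted over the list alone, camera adjusted p = 5.7e-07, adjusted p = 0.27 with an estimated correlation). Higher on the left as lists were NF-kB targets (median 0.34, adjusted p = 0.00049, adjusted p = 0.47 with an estimated correlation) and immediate early factors (0.38, adjusted p = 0.00099, adjusted p = 0.67 with an estimated correlation). Apoptosis genes were higher too (0.21, adjusted p = 0.0053, adjusted p = 0.47 with an estimated correlation), as were type I cell markers (0.24, adjusted p = 0.0053, adjusted p = 0.47 with an estimated correlation). Oxidative phosphorylation genes were lower (-0.11, adjusted p = 0.00049, adjusted p = 0.67 with an estimated correlation), in arrays with lower cardiac markers (-1.04, adjusted p = 0.0065, adjusted p = 0.67 with an estimated correlation). Mast cell markers were lower by a median of -0.45 (adjusted p = 0.008, adjusted p = 0.27 with an estimated correlation). No member of these 7 lists passed over all genes, and over the list alone 1 apoptosis gene was higher and 3 mast cell genes were lower. Fry and camera with an estimated correlation each called 0 lists in this comparison. Of the 10 splits of these arrays into 3 against 3, 5 called at least 8 lists, the real split among them (highest other 12). Chance was therefore not excluded for the number of lists called. Without right 30 min replicate 3, whose actin ratio was 2.93, 4 of the 8 list calls remained, those of the immediate early, NF-kB, apoptosis and mast cell lists having ended, and without left 30 min replicate 3 there were 13. The cardiac call ended without any 1 of 4 arrays, and the type I and mast cell calls without the 3 arrays of high actin ratio.

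With left and right lungs of the same number as a replicate block by duplicateCorrelation 13 probe sets passed, and 0 with a fixed block. Single arrays moved the count of 4 to 1 without left 30 min replicate 3, 2 without right replicate 3, 8 without right replicate 2 and 16 without right replicate 1. None of the 4 passed with only these groups in the fit. Without the 3 arrays of high actin ratio 1 left lung, assumed to vary like the other groups, stood against 2 right lungs, and 0 passed. Mylip (0.93 ± 0.21, SE), Mief1 (-0.60 ± 0.20), Rnf144b (-0.82 ± 0.20) and Id1 (-1.03 ± 0.19) kept their direction in that fit, and with so few arrays the lost calls do not show a dependence on RNA quality.

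At 3 h the heat shock genes set the clamped left lungs apart from the unclamped right lungs (n = 3 against 3). Hspa1a was 14.9-fold higher in the left than in the right lungs (log2 difference 3.90 ± 0.31, SE, limma adjusted p = 1.9e-06), Dnaja1 5.72-fold (2.52 ± 0.18, adjusted p = 5.2e-07), Dnajb1 5.15-fold and the small heat shock protein Hspb1 5.37-fold. The stress factor Atf3 (8.37-fold, adjusted p = 0.032), Fosb (23.4-fold, adjusted p = 0.034) and Tfpi2 (5.59-fold, adjusted p = 0.033) were also higher. Striated muscle genes differed in the other direction. The mean signal on the left and on the right was 15.7 ± 3.92 and 731 ± 785 for myoglobin Mb (SD, adjusted p = 0.031) and 25.8 ± 5.46 and 577 ± 543 for cardiac troponin Tnni3 (SD, adjusted p = 0.034). Fabp3 was 8.76-fold, Ckmt2 5.64-fold and Smpx 3.36-fold lower on the left. The calls of Fosb, Atf3, Tfpi2, Mb, Fabp3, Ckmt2 and Smpx each ended without any 1 of 4 arrays, and that of Tnni3 without any 1 of 5, and all 5 muscle calls ended with the cardiac marker mean as a covariate. That covariate is itself a mean of muscle genes, so the loss of the muscle calls follows largely by construction.

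Of 18 heat shock genes 12 were higher in the left lungs at 3 h (15 adjusted over the list alone, median 0.98, camera adjusted p = 3.1e-29, adjusted p = 0.0031 with an estimated correlation). Of 27 unfolded protein and integrated stress response genes 5 were higher (7 over the list alone, 0.29, adjusted p = 1.2e-08, adjusted p = 0.039 with an estimated correlation), among them Ddit3 at 2.58-fold and Hspa5 at 2.05-fold. NF-kB targets were higher in 7 of 16 (10 over the list alone, adjusted p = 7.5e-11, adjusted p = 0.12 with an estimated correlation). Immediate early factors were higher in 4 of 24 (10 over the list alone, adjusted p = 6.4e-10, adjusted p = 0.2 with an estimated correlation). Cytokines were higher in 3 of 21 (11 higher and 1 lower over the list alone, adjusted p = 5.5e-06, adjusted p = 0.16 with an estimated correlation). Hypoxia and glycolysis genes were higher in 4 of 28 (6 over the list alone, adjusted p = 6.2e-06, adjusted p = 0.16 with an estimated correlation). Coagulation genes were higher in 2 of 21 (3 over the list alone, adjusted p = 9.8e-05, adjusted p = 0.2 with an estimated correlation). Apoptosis genes were higher in 3 of 18 (5 over the list alone, adjusted p = 9e-05, adjusted p = 0.16 with an estimated correlation). Interferon genes were higher in 1 of 23 (1 over the list alone, adjusted p = 0.0044, adjusted p = 0.36 with an estimated correlation). Matrix genes were higher as a list (0 of 21, and 4 over the list alone, adjusted p = 0.026, adjusted p = 0.22 with an estimated correlation).

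Alveolar type II markers were lower on the left at 3 h, by a median of -0.51, with Sftpa1 1.45-fold lower as the 1 of 14 that passed over all genes (10 adjusted over the list alone, camera adjusted p = 1.4e-06, adjusted p = 0.16 with an estimated correlation). Oxidative phosphorylation genes were lower by a median of -0.29 (2 of 83 passed, 7 over the list alone, adjusted p = 4.7e-10, adjusted p = 0.2 with an estimated correlation), beside a cardiac marker median of -2.69 (3 of 12 passed, 11 over the list alone, adjusted p = 4.9e-08, adjusted p = 0.2 with an estimated correlation). Ribosomal protein genes were lower as a list (median -0.12, or -0.06 relative to all probe sets, 0 of 41, adjusted p = 0.02, adjusted p = 0.71 with an estimated correlation), and turned direction without left 3 h replicate 3. So were monocyte and macrophage markers (median -0.20, 0 of 12, and 3 over the list alone, adjusted p = 0.049, adjusted p = 0.2 with an estimated correlation). Over all probe sets 173 were higher and 67 lower, 72.1% of the calls being higher and 85.0% with each array centred on its median. The count of 240 moved to 35 without left 3 h replicate 1, 61 without right replicate 1, 107 without right replicate 2, 461 without right replicate 3, 33 with the cardiac covariate and 27 with only these groups in the fit. With the replicate number as a fixed block 16 passed, although the labels do not say that these numbers mark rats. The interferon, matrix, ribosomal and macrophage list calls each ended without at least 1 single array.

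**Figure D4:**
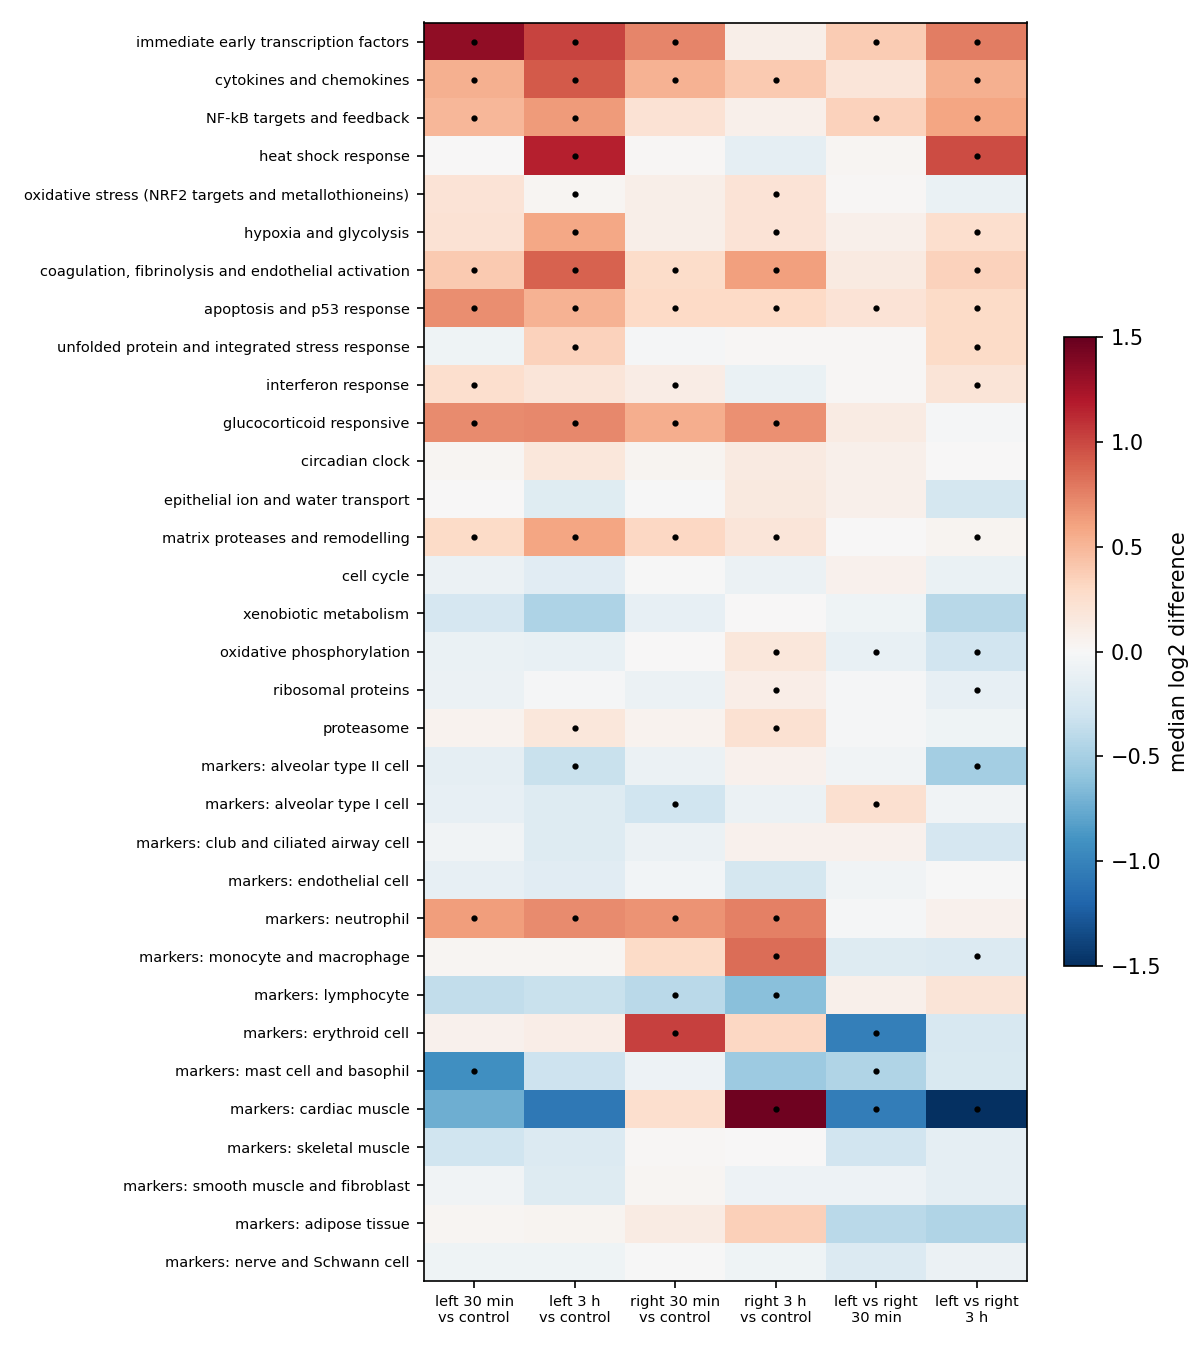
Median log2 difference of the measured members of each gene list (rows) in the 4 comparisons with control and the 2 comparisons of left with right (columns), colour scaled from -1.5 to 1.5, with a dot where the list passed the camera test at adjusted p 0.05. The heat shock row is near 0 except in the left lungs at 3 h (1.17) and left versus right at 3 h (0.98).

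Between 30 min and 3 h of reperfusion the left lungs gained chaperones (n = 3 against 3). Hspa1a rose 5.85-fold (log2 difference 2.55 ± 0.31, SE, limma adjusted p = 0.00022), Hsph1 4.98-fold, Dnaja1 4.18-fold (2.06 ± 0.18, adjusted p = 6e-06), Hspb1 4.08-fold and Dnajb1 3.69-fold. Of 18 heat shock genes 13 rose (15 adjusted over the list alone, camera adjusted p = 5.9e-26, adjusted p = 0.0054 with an estimated correlation). Of 27 unfolded protein genes 6 rose and 1 fell (10 and 1 over the list alone, adjusted p = 4.1e-08, adjusted p = 0.041 with an estimated correlation). Hypoxia and glycolysis genes rose in 4 of 28 (10 over the list alone, adjusted p = 3.8e-07, adjusted p = 0.12 with an estimated correlation), with the collagen hydroxylase P4ha1 at 2.41-fold. Proteasome genes rose in 2 of 34 (2 over the list alone, adjusted p = 0.00029, adjusted p = 0.48 with an estimated correlation). The interferon-induced Mx2 fell 2.77-fold (-1.47 ± 0.24, adjusted p = 0.0034), and Skic2 (3.41-fold), Armcx4 (3.38-fold) and Dmtn (3.18-fold) fell more. The mean signal of Arhgef40 fell from 186 ± 55.6 to 25.9 ± 9.64 (SD, adjusted p = 0.026).

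Other lists had higher medians at 3 h than at 30 min in the left lungs. Coagulation genes rose in 2 of 21 (2 over the list alone, camera adjusted p = 0.0013, adjusted p = 0.47 with an estimated correlation). No NF-kB target passed over all genes (4 of 16 over the list alone, adjusted p = 5e-04, adjusted p = 0.47 with an estimated correlation). Neutrophil markers (0 of 11, adjusted p = 0.0072, adjusted p = 0.78 with an estimated correlation) and macrophage markers (0 of 12, adjusted p = 0.047, adjusted p = 0.47 with an estimated correlation) passed as lists only. So did matrix genes (0 of 21, adjusted p = 0.047, adjusted p = 0.47 with an estimated correlation) and ribosomal genes (0 of 41, adjusted p = 0.013, adjusted p = 0.92 with an estimated correlation). The ribosomal median, 0.11 relative to all probe sets, was 0 under quantile normalization, which ended that call. Type II cell markers were lower as a list (0 of 14, and 1 higher and 4 lower over the list alone, adjusted p = 0.047, adjusted p = 0.85 with an estimated correlation). Each of these 7 calls ended when 1 array was left out, and the neutrophil list turned direction without the 3 arrays of high actin ratio, where the coagulation, NF-kB, macrophage, matrix and type II cell calls ended too. Over all probe sets 168 were higher and 198 lower, 45.9% of the calls being higher and 63.6% with each array centred on its median. The 366 calls fell to 27 with only these groups in the fit, and to 37 with all arrays and the actin ratio as a covariate. They fell to 19 without the 3 arrays of high actin ratio, when the left 30 min group was a single lung assumed to vary like the other groups. In that fit Hspb1 (log2 difference 1.65 ± 0.32, SE, from 2.03 ± 0.23), Mx2 (-1.40 ± 0.37 from -1.47 ± 0.24), Arhgef40 (-1.94 ± 0.54 from -2.04 ± 0.45), Skic2 (-1.79 ± 0.60 from -1.77 ± 0.45), Armcx4 (-1.76 ± 0.49 from -1.76 ± 0.38) and Dmtn (-1.61 ± 0.45 from -1.67 ± 0.30) did not pass. Single arrays left 53 (left 3 h replicate 1), 145 (3 h replicate 2), 776 (3 h replicate 3), 55 (30 min replicate 1) and 98 (30 min replicate 3).

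In the right lungs few genes moved between 30 min and 3 h (n = 3 against 3). The fatty acid receptor Cd36 rose 2.34-fold (log2 difference 1.23 ± 0.24, SE, limma adjusted p = 0.04), while the leukocyte antigen Cd52 fell 3.36-fold (-1.75 ± 0.29, adjusted p = 0.023), Alox15 3.20-fold, the red cell enzyme Bpgm 3.04-fold, Ube2o 2.83-fold and Rbm38 2.77-fold. Erythroid markers fell in 2 of 8 (5 adjusted over the list alone, camera adjusted p = 0.00069, adjusted p = 0.48 with an estimated correlation). Mx2 fell as the 1 of 23 interferon genes to pass (3 over the list alone, adjusted p = 0.00046, adjusted p = 0.48 with an estimated correlation). Immediate early factors had a median of -0.43 (0 of 24, and 1 lower over the list alone, adjusted p = 0.00046, adjusted p = 0.56 with an estimated correlation).

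Other lists were higher at 3 h than at 30 min in the right lungs, mostly with no member passing. Oxidative phosphorylation genes were higher (0 of 83, camera adjusted p = 4.4e-08, adjusted p = 0.48 with an estimated correlation), beside a cardiac marker median of 1.20 (0 of 12, adjusted p = 0.00011, adjusted p = 0.51 with an estimated correlation). Ribosomal (0 of 41, adjusted p = 1e-07, adjusted p = 0.48 with an estimated correlation) and proteasome genes (0 of 34, adjusted p = 0.00011, adjusted p = 0.48 with an estimated correlation) were too. Macrophage markers had 1 of 12 higher over the list alone (adjusted p = 0.00046, adjusted p = 0.15 with an estimated correlation), and neutrophil markers 0 of 11 (adjusted p = 0.0095, adjusted p = 0.56 with an estimated correlation). Type I cell markers passed as a list (0 of 10, adjusted p = 0.0095, adjusted p = 0.48 with an estimated correlation). Type II cell markers rose in 1 of 14 (1 over the list alone, adjusted p = 0.03, adjusted p = 0.56 with an estimated correlation). Oxidative stress genes passed as a list (0 of 17, adjusted p = 0.039, adjusted p = 0.48 with an estimated correlation). In total 4 probe sets were higher and 17 lower, with 1432 of 10533 at an unadjusted p under 0.05, where chance alone gives about 1 in 20. The count fell to 0 without right 30 min replicate 3, whose actin ratio was 2.93, with the cardiac covariate, or with only these groups in the fit. Without the 3 arrays of high actin ratio, of which only right 30 min replicate 3 is in this comparison, Cd36 stood at 0.94 ± 0.21 (SE), Cd52 at -1.32 ± 0.22, Alox15 at -1.24 ± 0.25, Bpgm at -1.20 ± 0.26 and Ube2o at -1.10 ± 0.21, and neither these nor Rbm38 passed. The cardiac and oxidative stress list calls ended without right 30 min replicate 3, and the immediate early, type II cell and neutrophil calls each without any 1 of 2 or more other arrays. Other single arrays left 5 (right 3 h replicate 1), 6 (3 h replicate 2), 36 (3 h replicate 3) and 60 (30 min replicate 1).

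The change of the left-right difference between 30 min and 3 h was tested directly, and chaperones again led it. Hspa1a gained 3.43 ± 0.44 (SE) on the log2 scale (limma adjusted p = 0.0014), Dnaja1 2.48 ± 0.25 (adjusted p = 0.00014), Hspb1 2.40 ± 0.32, Hsph1 2.30 ± 0.37 and Dnajb1 2.04 ± 0.27, while Mylip lost (-1.09 ± 0.19, adjusted p = 0.021) and Patz1 too (-0.79 ± 0.15, adjusted p = 0.037). Heat shock genes gained in 8 of 18 (12 adjusted over the list alone, camera adjusted p = 7.1e-31, adjusted p = 0.0024 with an estimated correlation). Unfolded protein genes gained in 1 of 27 (5 over the list alone, adjusted p = 1e-07, adjusted p = 0.049 with an estimated correlation).

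Other lists passed this test of the change, nearly all with no member passing over all genes. Hypoxia genes gained in 1 of 28 (2 over the list alone, camera adjusted p = 1e-04, adjusted p = 0.36 with an estimated correlation). Gains as lists were found in NF-kB targets (0 of 16, adjusted p = 0.00031, adjusted p = 0.49 with an estimated correlation) and immediate early factors (0 of 24, adjusted p = 0.001, adjusted p = 0.61 with an estimated correlation). Erythroid markers gained (0 of 8, and 4 over the list alone, adjusted p = 0.0024, adjusted p = 0.49 with an estimated correlation). Cytokines gained as well (0 of 21, and 1 over the list alone, adjusted p = 0.006, adjusted p = 0.55 with an estimated correlation). So did coagulation (0 of 21, adjusted p = 0.04, adjusted p = 0.61 with an estimated correlation) and matrix genes (0 of 21, adjusted p = 0.046, adjusted p = 0.49 with an estimated correlation). Type II cell markers moved the other way (median -0.42, 0 of 14, and 1 lower over the list alone, adjusted p = 5.7e-05, adjusted p = 0.36 with an estimated correlation). Epithelial ion and water transport genes did so too (-0.32, 0 of 15, adjusted p = 0.016, adjusted p = 0.36 with an estimated correlation). Oxidative phosphorylation genes lost (-0.16, 0 of 83, adjusted p = 0.0022, adjusted p = 0.61 with an estimated correlation), beside cardiac markers (-1.63, 0 of 12, adjusted p = 0.001, adjusted p = 0.61 with an estimated correlation). In total 22 probe sets were higher and 2 lower, with 740 of 10533 at an unadjusted p under 0.05, where chance alone gives about 1 in 20. With only these 4 groups in the fit 8 passed, with the actin ratio as a covariate 14, and with the cardiac marker mean as a covariate 13. Without the 3 arrays of high actin ratio, with 1 left and 2 right lungs at 30 min and the lone lung assumed to vary like the other groups, 5 passed. Hspb1 (2.04 ± 0.41, SE), Hsph1 (2.79 ± 0.47) and Dnajb1 (2.02 ± 0.36) were then not among them. The Mylip and Patz1 calls each ended without any 1 of several arrays. Of the 13 list calls 7 remained without right 3 h replicate 2, and there were 20 without left 30 min replicate 2. The immediate early, cytokine, coagulation, matrix, erythroid, ion transport, oxidative phosphorylation and cardiac calls each ended without at least 1 single array. All of these but the immediate early and oxidative phosphorylation calls also ended without the 3 arrays of high actin ratio. For probe sets, single arrays left 15 (left 3 h replicate 1), 15 (left 30 min replicate 1), 13 (left 30 min replicate 3), 10 (right 3 h replicate 1), 14 (right 30 min replicate 2) and 14 (right 30 min replicate 3).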

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

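Of the tests in this part, those of RNA quality (other than the actin covariate for the shared changes), neutrophil content and cardiac muscle content for the left-right differences, those of shared controls and of the handling of controls, and the reassignment of sides within each time were chosen after the results were seen.

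Among the 6 controls, 1 array lay far from the others in 12 of 102 sets of values examined, and chance alone gives about 1 in 20, or 5.1. On the log2 scale these were control replicate 1 in Abca3 (11.40), Nfix (9.66), Prkaa2 (6.99) and Tfpi2 (6.74), replicate 2 in S100a8 (9.49) and S100a9 (11.21), replicate 3 in Arhgef40 (7.03), replicate 5 in Dnaja1 (11.13), Hsph1 (10.73), Klf9 (10.52) and Rbm38 (8.31), and replicate 6 in Fkbp5 (9.06).

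The left-right difference changed between 30 min and 3 h, by a test of that change, in 24 probe sets. The named genes were Hspa1a (3.43), Dnaja1 (2.48), Hspb1 (2.40), Hsph1 (2.30), Dnajb1 (2.04), Mylip (-1.09) and Patz1 (-0.79). The lists, with the median of their members, were heat shock (1.10), erythroid markers (0.75), immediate early factors (0.38), NF-kB targets (0.35), the unfolded protein response (0.32), cytokines (0.30), hypoxia and glycolysis (0.30), coagulation (0.29), matrix proteases (0.22), oxidative phosphorylation (-0.16), epithelial ion and water transport (-0.32), type II cell markers (-0.42) and cardiac markers (-1.63). With sides and times reassigned, 8 of 100 splits gave as many probe sets (real 24, highest other 909) and 37 as many lists (real 13, highest other 19). With sides reassigned within each time 15 of 100 gave as many probe sets (highest other 226) and 33 as many lists (highest other 19). Such splits cannot decide on chance, because a reassignment can turn a difference between sides or times into the tested change. Chance was therefore not excluded for either number. Which structure of the arrays lay behind the splits that call many times the real count was not tested.

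Heat shock genes were higher in the left than in the right lungs at 3 h, their mean by 1.36 ± 0.12 (SE) on the log2 scale. The actin ratio of all 3 left lungs lay inside the range of the right lungs, but the GAPDH ratio of 2 (1.38 and 1.31) lay above it (1.07 to 1.30). With both ratios as covariates the difference was 1.39 ± 0.13 (SE), against RNA quality as the cause. The neutrophil marker mean differed by only 0.08 ± 0.43 (SE), and with the cardiac marker mean as a covariate the heat shock difference was 1.40 ± 0.16 (SE). A response to the clamp and the return of blood flow, which the design assigns to the left lung, is a hypothesis found and tested on the same data. Because all clamped lungs were left lungs, a difference between the sides at 3 h stays open and was not tested.

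Cardiac muscle markers were lower in the left than in the right lungs at 3 h, their mean by -2.47 ± 0.79 (SE), and oxidative phosphorylation genes by -0.31 ± 0.08 (SE). With the actin and GAPDH ratios as covariates these differences were -1.97 ± 0.72 (SE) and -0.27 ± 0.08 (SE), against RNA quality as the whole cause. With the cardiac marker mean as a covariate the oxidative phosphorylation difference was -0.21 ± 0.10 (SE), and for these genes a different share of cardiac muscle in the lung pieces and a change within lung cells cannot be told apart, because the error is too large. A difference between the sides stays open and was not tested.

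Changes against control were shared by the left and right lungs. With the controls split between the sides the covariance of the log2 differences at 3 h was 0.176, against 0.185 with shared controls, and with the actin ratio as a covariate it was 0.195. Less the covariance expected from error, it was 0.145 at 30 min and 0.184 at 3 h with the actin and GAPDH ratios as covariates (0.134 and 0.172 without), and at least 0.117 and 0.150 whichever array was left out, so RNA quality by these ratios does not account for it at either time, nor do shared controls at 3 h. The controls stood apart from the nearest operated array by 21.6 on the first principal component, and a batch or handling difference of the controls cannot be told apart from anaesthesia, surgery and ventilation, because no control lung had these. A response of the unclamped lung stays open and was not tested.

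Other splits of the same arrays were refitted for each count. For the comparisons with control, only the real split, 1 of 84, reached the number of probe sets: left 30 min 2099 (highest other 3), left 3 h 3977 (2), right 30 min 1407 (6) and right 3 h 2255 (4). That share is under 0.05 and the smallest that 84 splits allow. Splits that mix operated and control lungs add their difference to the spread, which lowers the other counts, so these are no level expected by chance. Chance cannot be excluded for the number of lists called: 28 of 84 splits gave as many as the real 10 (highest other 13) for left 30 min, 25 as many as 14 (19) for left 3 h, 17 as many as 11 (18) for right 30 min and 12 as many as 14 (17) for right 3 h. The 10 splits of 3 against 3 arrays are too few for a share under 0.05. For probe sets, 2 splits reached the real value in left versus right at 30 min (real 4, highest other 62), 1 at 3 h (240 and 30), 1 in the left lungs over time (366 and 10) and 1 in the right lungs over time (21 and 8). For lists these numbers were 5 (8 and 12), 4 (15 and 16), 5 (11 and 16) and 3 (12 and 14). The split that gave 62 probe sets put left 30 min replicates 1 and 3 with right 30 min replicate 3, the 3 arrays of high actin ratio. Of the splits at 30 min that part all 3 number pairs, the real one gave 4 and the others 0.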

How the results depend on the processing

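The fits with the actin ratio, the cardiac marker mean or without the arrays of high actin ratio, and the list tests without single arrays, were chosen after the results were seen. The counts below that moved past 1.5-fold did so for a cause that was not tested, except that a 2-fold requirement, fewer arrays or a changed set of tested probe sets act by construction. With at least a 2-fold change required, the counts were 369 (left 30 min versus control), 660 (left 3 h), 269 (right 30 min), 371 (right 3 h), 2 (left versus right at 30 min), 80 (left versus right at 3 h), 98 (left over time) and 12 (right over time). Without the low-signal filter left versus right at 3 h gave 138, left over time 192 and right over time 10. The stricter filter gave 9 for left versus right at 30 min and 32 for right over time. Array weights gave 15, 450 and 69 for left versus right at 30 min, at 3 h and right over time. A pseudocount 4 times as large gave 8 for left versus right at 30 min, and centring on the median gave 13 for right over time. With only the groups of the comparison in the fit, left versus right gave 0 at 30 min and 27 at 3 h, left over time 27, right over time 0 and the change of the left-right difference 8. With the replicate number as a block, left versus right at 30 min gave 13 by duplicateCorrelation and 0 with a fixed block, and at 3 h 16 with a fixed block, 11 of them among the 240. The block correlation was 0.219 at 30 min, -0.0465 at 3 h and 0.0745 over all arrays. Without the arrays of high actin ratio, which leaves 1 left and 2 right lungs at 30 min, the lone left lung being assumed to vary like the other groups, the counts were 637 (left 30 min), 0 (left versus right at 30 min), 19 (left over time), 0 (right over time) and 5 (change of the difference), and with the actin covariate 1194 (left 30 min), 9 (left versus right at 30 min), 37 (left over time) and 14 (change of the difference). With the cardiac covariate they were 1328 (right 3 h versus control), 8 and 33 (left versus right at 30 min and 3 h), 0 (right over time) and 13 (change of the difference). The number of lists called fell to 7 for left over time in each of the actin settings. With an estimated correlation it was 0 in the 4 comparisons with control, left versus right at 30 min and right over time, and 2 in left versus right at 3 h, left over time and the change of the difference. Fry gave 6 (right 30 min), 0 (left versus right at 30 min), 3 (left over time), 1 (right over time) and 2 (change of the difference). List tests that reversed were ribosomal genes in left versus right at 3 h without left 3 h replicate 3 (adjusted p = 0.88, from 4.5e-06 to 0.88 over the arrays left out singly) and in right 3 h versus control under quantile normalization (0.98), neutrophil markers in left over time without the arrays of high actin ratio (0.48), and cardiac markers with their own mean as a covariate, which removes them by construction (0.92 and 0.94 in left versus right at 30 min and 3 h, 0.91 in the change of the difference). Leaving out 1 array at a time, the counts ranged from 1309 to 1913 (left 30 min), 2299 to 4052 (left 3 h), 811 to 1190 (right 30 min), 1417 to 1981 (right 3 h), 1 to 16 and 35 to 461 (left versus right at 30 min and 3 h), 53 to 776 (left over time), 0 to 60 (right over time) and 10 to 30 (change of the difference). The lists called ranged from 8 to 13, 14 to 15, 9 to 16 and 11 to 16 in the comparisons with control, 4 to 13 and 13 to 15 in left versus right, 4 to 12 and 10 to 15 over time and 8 to 20 in the change of the difference. The arrays that moved a list count past 1.5-fold were left 3 h replicate 1 (4) and left 30 min replicate 3 (7) in left over time, left 30 min replicate 3 (13) and right 30 min replicate 3 (4) in left versus right at 30 min, and left 30 min replicate 2 (20) and right 3 h replicate 2 (8) in the change of the difference. Every named gene kept its direction in every setting that was fitted.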

Other observations

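Several gene groups of the lung passed camera in no comparison with control, although single members did. Of 16 endothelial cell markers 2 rose and 5 fell in the left lungs at 30 min (camera adjusted p = 0.58), where 2 of 3 arrays had a high actin ratio (in the lung without it Flt1 stood at -0.18 ± 0.21 and Calcrl at -0.50 ± 0.29, SE, against -0.68 ± 0.21 and -1.03 ± 0.26 with all arrays, and neither passed), 2 rose and 3 fell at 3 h (adjusted p = 0.78), and in the right lungs 1 rose and 4 fell at 30 min (adjusted p = 0.72) and 2 rose and 3 fell at 3 h (adjusted p = 0.66). Of 16 xenobiotic metabolism genes 2 rose and 7 fell in the left lungs at 3 h (median -0.46, adjusted p = 0.6), and of 24 smooth muscle and fibroblast markers 6 fell (median -0.19, adjusted p = 0.52). Fry, which asks only whether the members move one way and not whether they do so more than other genes, called both lower there (adjusted p = 0.047 and 0.0031). Over all 7728 genes 1044 rose and 1864 fell in that comparison, so 6 of 24 falling is near the share of all genes. Of 9 club and ciliated airway cell markers 1 fell in the left lungs at 3 h and none moved in the other 3 groups (adjusted p = 0.77 in the left lungs at 3 h).

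In the left lungs at 3 h the cell cycle genes were divided, 3 rising and 3 falling of 20 (adjusted p = 0.81), as were circadian clock genes, 1 rising and 2 falling of 12 (adjusted p = 0.49). Skeletal muscle markers (1 up and 1 down of 6, adjusted p = 0.81), adipose markers (2 down of 8, adjusted p = 0.78) and nerve and Schwann cell markers (1 down of 5, adjusted p = 0.98) did not pass camera there. None of these counts is large beside the 1044 higher and 1864 lower of all 7728 genes in that comparison.

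The first principal component of the 18 arrays held 36.0% of the variance and the second 12.6%. In the left lungs 666 probe sets were higher and 810 lower than control at both times, and in the right lungs 394 were higher and 513 lower at both times.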
